A study of Mus musculus with 6 samples.

How the data were processed

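The samples were LARP1 immunoprecipitates from wild-type mouse DRG, 3 libraries labelled injured and 3 labelled uninjured. Per the labels' protocols, DRG lysate was precipitated with an anti-LARP1 antibody, RNA was purified on RNeasy columns, and libraries were made with a nanopore cDNA-PCR barcoding kit, which amplifies the cDNA; molecular identifiers were not used here. The deposited values are estimated counts per Ensembl gene identifier, not normalized, and per the submitters' processing notes minimap2 and Salmon were used with the mouse genome build GRCm39 (mm39); versions, parameters, the annotation release and any filter on reads or genes are not given in the sources used here. Salmon shares reads among similar transcripts by estimation, so counts of near-identical or overlapping genes are uncertain. All values were whole numbers, so rounding before the count tests changed none. The table held 16976 identifiers, 3740 of them with no count in the 6 libraries; 0 rows named no gene and 0 further columns were left unused.

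Groups and replicate numbers were taken from the sample titles, and each column was matched to its sample by library name. Agreement between the libraries of a group was tested by the chi-square statistic of each gene with at least 15 counts in the group, with each library's total as exposure, and set against 100 random divisions of the summed counts. Because the libraries agreed nearly within sampling noise, the counts of a group were summed and counted as 1 sample. Levels are CPM, scaled to a group's summed total, with 95% exact Poisson intervals, and ratios of CPM have 95% exact Clopper-Pearson intervals computed from the share of a gene's counts that came from the injured group. A group with 0 counts was set to a floor of 3 counts over the group, and the ratio against it, which takes the other group's level as measured, is given as at least that value. These intervals cover counting error only. The depth of 116186 to 116608 counts per uninjured library and 211337 to 211879 per injured library limits the precision: 3 counts correspond to 8.60 CPM in the summed uninjured group and 4.73 CPM in the summed injured group.

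The test fixed before the data were examined was edgeR 4.0.16's quasi-likelihood test (R 4.3.3) on the 6 libraries with TMM normalization, the filterByExpr filter and a Benjamini-Hochberg threshold of 0.05. It is given as a test of the reads of 2 samples, and no p-value of a single gene is given. The reason is that the libraries of a group were counted as 1 sample, although their origin is not known. TMM factors were 0.960 to 0.965 in the uninjured and 1.04 in the injured libraries; with library sizes taken over the tested genes, the ratios of CPM by full library totals lay 0.07 above those on the scale of the test, in log2. Fold sizes on the scale of the test were added after the data were seen. In data simulated from these libraries with known changes, the test of injured against uninjured libraries was run on 3049 genes. Filter and test together recovered 17.9% of 67 genes changed 1.5-fold, 61.2% of 67 changed 2-fold and 83.3% of 66 changed 4-fold. Any changed gene that the filter removed counted as missed. Of the test's 112 calls, 4 were unchanged genes. The simulated spread was that between libraries (coefficient of variation 3.57%), so these shares hold only for reads of the same 2 samples. Far fewer genes were changed there than the 1485 called in the data, so recovery in the data can differ.

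The rule fixed beforehand named up to 12 genes per direction by log2 fold change among genes past the threshold, with every injured library above (or below) every uninjured one and a mean of at least 10 counts, but left out identifiers without a symbol. Since the gene table used here lists no Ensembl identifiers and no identifier was paired with a symbol, the first 2 genes per direction were named by identifier. They were ranked by the ratio of CPM with the floor in place of 0, a choice made after the data were seen, because a fitted fold change against 0 counts depends on the prior count; ranked by the fitted values, ENSMUSG00000024907 would not have been among the 2 higher genes named. The 24 gene lists fixed beforehand (pathways and markers of cell types), the tests of shares of counts in such lists, and the level of Larp1 itself were not analysed here: they need a table that pairs Ensembl identifiers with symbols.

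The alternatives tried were DESeq2 1.42.0, limma-voom (limma 3.58.1), other size factors, library totals over the tested genes without TMM factors, other filters on low counts, the shared replicate number as a term and leaving out each library. DESeq2 replaced its parametric dispersion trend by a local fit. Alternatives added after the data were seen were an exact binomial test on the summed counts, edgeR's exact test with an assumed coefficient of variation of 0.2 or 0.4, injured libraries thinned to the uninjured depth, and removal of genes whose libraries disagreed. Equal-depth values came from random draws without replacement (numpy 2.4.6) and intervals from scipy 1.17.1; the equal-depth counts of genes absent from 1 group and the shares by identifier number were added after the data were seen.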

Results

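RNA that co-precipitated with LARP1 was measured in mouse dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, with and without prior sciatic nerve injury. LARP1 is an RNA-binding protein known for binding mRNAs with a terminal oligopyrimidine tract, many of which encode ribosomal proteins and translation factors. LARP1 was pulled down by antibody from lysates of wild-type DRG, and the RNA recovered with it was converted to cDNA, amplified, barcoded and sequenced as nanopore reads. The design has 2 groups, injured and uninjured, each with 3 libraries labelled as replicates. Estimated counts were given for 16976 Ensembl gene identifiers, of which 13236 had a count in at least 1 library. The uninjured libraries held 116233, 116608 and 116186 counts, and the injured libraries held 211879, 211337 and 211399. No total RNA or control immunoprecipitate was analysed here, so each value is the level of a gene's RNA in the LARP1 precipitate and not its enrichment over the tissue.

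The 3 libraries of a group differed by little more than the sampling noise of counting and were therefore counted as 1 sample. Their totals spanned 0.363% of the mean in the uninjured group and 0.256% in the injured group. The SD of the totals was 231 counts in the uninjured group and 297 in the injured group. In neither group did the totals differ beyond a random division of 1 pool of reads into 3 parts (chi-square test of the totals on counts, p = 0.632 and p = 0.660). Over the genes with at least 15 counts in a group, the variance between libraries was 1.16 times counting noise for 3827 genes in the uninjured group and 1.12 times for 6152 genes in the injured group. It was 1.05 times in the uninjured group and 1.06 times in the injured group without the genes whose libraries disagreed at a chi-square p under 1e-04, of which there were 19 and 22. Among all genes with at least 1000 counts in the group, which resolve a small spread best, it was 1.44 times for 27 genes and 1.70 times for 57 genes. Disagreeing genes were kept in these 2 values. One was ENSMUSG00000045690, with 511, 396 and 537 counts in the uninjured and 778, 504 and 555 in the injured libraries. The values without it were not computed. Its chi-square across libraries accounts for most of the excess over counting noise in both values. They therefore reflect this gene more than abundant genes in general. The coefficient of variation between libraries, beyond counting, was 3.57% in edgeR's fit. Nothing in the labels says that the libraries came from separate animals. With 1 sample per group, the differences below have no replicate check, and group cannot be told apart from any batch in which the group was prepared or sequenced. The intervals below cover counting error only, since PCR reads counted without molecular identifiers are not independent molecules.

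**Figure D1:**
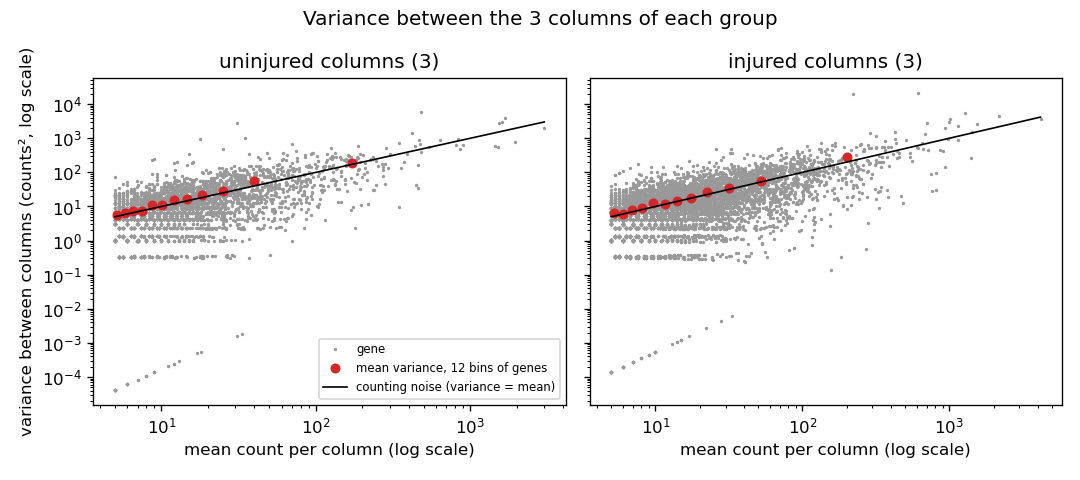
Variance between the 3 libraries of a group (vertical axis, squared counts, log scale) against the mean count per library (horizontal axis, log scale) for genes with at least 15 counts in the group; grey points are genes (those with equal libraries are not drawn), red points are means over bins of genes, and the line is pure counting noise. The red points lie close to the line in both groups, and the overall ratio was 1.16 in the uninjured and 1.12 in the injured group.

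The comparison the design implies, injured against uninjured, asks which RNAs were more or less abundant in the LARP1 precipitate after sciatic nerve injury. At an equal depth of 116186 counts per library, 28.3% to 28.8% of the counts lay in different genes between an injured and an uninjured library. The same measure was 12.4% between uninjured libraries and 13.2% to 13.4% between injured libraries. That is a spread between libraries counted as 1 sample, and it is not taken as one between samples. Across the 3158 genes that passed the filter on low counts, log2(CPM + 1) correlated between an uninjured and an injured library at a Pearson r of 0.580 to 0.603. It correlated at 0.849 to 0.851 between uninjured libraries and at 0.920 to 0.938 between injured libraries. Between the summed groups r was 0.672. Unlike the shares above, these correlations are at full depth, and the injured libraries are deeper. All are correlations across genes, which are not independent replicates.

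Of the 3158 genes tested, 1485 (47.0%) differed between the reads of the 2 groups in edgeR's quasi-likelihood test at a Benjamini-Hochberg threshold of 0.05. These were 786 genes with higher and 699 genes with lower levels in the injured precipitate. The balance of the directions depended on the setting, with 927 higher and 610 lower genes without TMM factors and 665 higher and 729 lower genes with limma-voom. The test compares the reads of these 2 samples, not the conditions, because the spread it uses is that between libraries that were counted as 1 sample. In a setting chosen after seeing the data, the counts of each group were summed and edgeR's exact test was used. An assumed coefficient of variation between animals took the place of the measured spread. With 0.2, 305 genes were higher and 176 lower, and with 0.4, 42 were higher and 5 lower. On the TMM scale of the test, the median ratio of injured to uninjured levels was 2.37 for the higher genes, and the median ratio of uninjured to injured levels was 2.05 for the lower genes. More than 2-fold differences were seen for 514 of the higher genes (65.4%) and 370 of the lower genes (52.9%), more than 4-fold differences for 159 and 45, and more than 8-fold differences for 65 and 8. By CPM of the full library totals, which lie 0.07 higher on the log2 scale, the medians were 2.50 and 1.94, with 560 (71.2%) and 320 (45.8%) genes past 2-fold. Over the 3158 genes tested, called or not, the quartiles of the log2 ratio on the TMM scale were -0.53 and 0.66. Of the higher genes, 22 had no count in the uninjured group and were ranked against its floor of 3 counts. No gene called lower had 0 counts in the injured group. This contrast is not at equal depth: the uninjured group held 349027 counts and the injured group 634615, so 0 counts are likelier in the uninjured group. Of the genes called, 7 were among those whose libraries disagreed within a group.

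**Figure D2:**
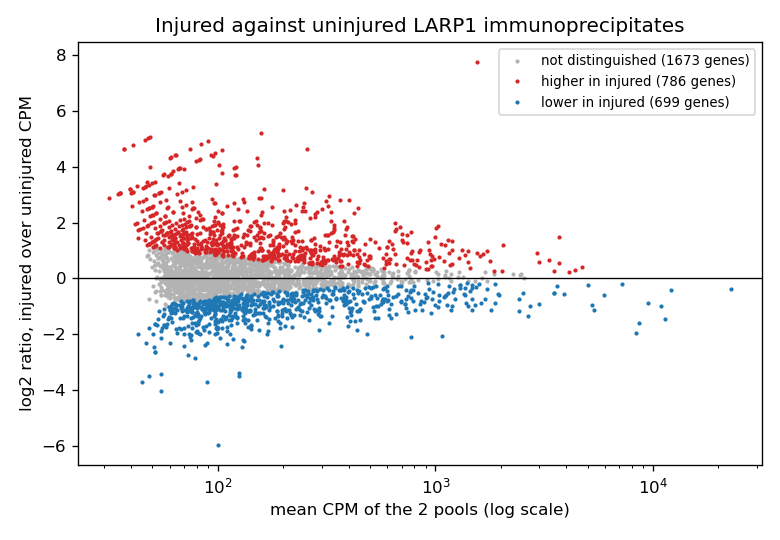
Log2 ratio of injured to uninjured CPM (vertical axis) against the mean CPM of the 2 groups (horizontal axis, log scale) for the 3158 genes tested, with the counts of each group summed over its libraries; colours mark the 786 higher and 699 lower genes of the test on reads, and a gene with 0 counts in a group is drawn at the floor of 3 counts. With that floor, the most distant gene above lies at a log2 ratio of 7.76 and the most distant below at -5.97.

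With the floor of 3 counts in place of 0, the highest ratio of CPM among the genes that differed was that of ENSMUSG00000024907; the ratios of genes with 0 uninjured counts have no upper limit, so their rank is open. ENSMUSG00000024907 was nearly absent from the uninjured precipitate. It had 2, 1 and 2 counts in the uninjured libraries and 637, 648 and 685 in the injured libraries. Summed by group, its level was 14.3 CPM without injury (95% exact Poisson interval 4.65 to 33.4) and 3104 CPM with injury (2969 to 3244), a ratio of 217 (95% exact interval 92.7 to 668). ENSMUSG00000106268 had no count in the 349027 counts of the uninjured group, where the floor of 3 counts corresponds to 8.60 CPM. It had 68, 68 and 65 counts in the injured libraries, or 317 CPM (274 to 364), so it was at least 36.8-fold higher against that floor with the injured level taken as measured. With the counting error of both groups, the exact 95% lower limit of the ratio was 29.7. In the other direction, ENSMUSG00000078735 had 20, 27 and 22 counts in the uninjured libraries and 0, 2 and 0 in the injured libraries. Its levels were 198 CPM (154 to 250) without and 3.15 CPM (0.382 to 11.4) with injury, and the uninjured level was 62.7 times the injured one, with an interval of 16.7 to 528 that reflects the 2 injured counts, both in the second library. In edgeR's fit its log2 fold change was -5.73, and it was -7.95 without that library, which left 0 injured counts and makes the fitted value no bound. ENSMUSG00000028949 had 26, 17 and 15 counts without and 0, 5 and 3 counts with injury. Its levels were 166 CPM (126 to 215) and 12.6 CPM (5.44 to 24.8), a ratio of uninjured to injured of 13.2 (6.27 to 32.0). Its log2 fold change in edgeR's fit was -3.71, and it was -3.10 without the first and -4.42 without the second injured library. With the injured libraries thinned to the uninjured depth, a setting chosen after seeing the data, it was -2.85. None of these 4 genes was among those whose libraries disagreed within a group. The table pairs its identifiers with no gene symbol, and the gene table used here lists no Ensembl identifiers, so 0 of the 16976 were matched and these genes are given by identifier.

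The 10 most abundant genes took a smaller share of the precipitate after injury. These genes, ranked by mean CPM, held 13.1% of the counts in the uninjured group and 7.26% in the injured group. All 10 were lower in the injured reads, by 1.15-fold to 3.88-fold, and the most abundant of them fell from 2.59% to 1.97% of the counts. They were also the 10 most abundant genes of the uninjured group alone, a selection that favours lower levels after injury. The injured group's own 10 most abundant genes held 7.72% of its counts. Of the 100 most abundant genes in each group, 69 were shared. The 100 most abundant genes of each group held 31.9% of the uninjured and 25.5% of the injured counts. Across the 3455 genes with a mean of at least 50 CPM, the log2 ratio had a Spearman correlation of -0.01 with mean CPM, across genes, which are not independent replicates. When these genes were divided into 5 classes of equal size by abundance, the median log2 ratio was 0.03 in the most abundant class, of which 51.5% were higher in the injured group, and 0.06 in the least abundant class. This selection was made after seeing the data, in place of a first one by a mean of at least 10 counts, which favours genes high in the deeper injured libraries. In the 2976 genes of the first selection the correlation was -0.13 and the median was 0.48 in the least and 0.03 in the most abundant class.

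More genes were represented in the injured precipitate, also at equal depth. A count was seen for 12511 genes in the injured group and 10636 in the uninjured group. When the injured counts were drawn down to the uninjured total of 349027, 11822 to 11922 genes had a count in 100 draws, a mean excess of 11.7% over the uninjured group. At that depth, a mean of 184 genes had at least 10 counts in the injured group and 0 in the uninjured group, and 58.6 genes had the opposite pattern, over 20 draws.

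**Figure D3:**
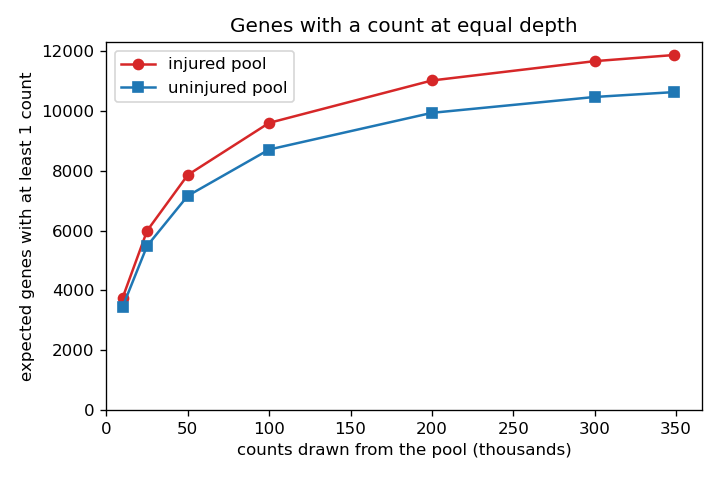
Expected number of genes with at least 1 count (vertical axis) against the number of counts drawn without replacement from each group's summed counts (horizontal axis, in units of 1000). The injured curve lies above the uninjured curve at every depth drawn, with 9605 against 8715 genes at 100000 counts and 11876 against 10636 at the full uninjured depth.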

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

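The exact binomial test, the assumed coefficients of variation, the thinning of injured libraries and the removal of disagreeing genes were chosen after seeing the data. The counts of 786 higher and 699 lower genes stayed within 1.5 times their values under 16 of the 18 alternatives, with 582 to 948 higher and 538 to 756 lower genes. No gene called in one direction was called in the other under any of the 18. The genes called changed more than their number. DESeq2, with 8618 genes tested, shared 544 of the 786 higher and 412 of the 699 lower calls. Without a filter, with 13236 genes tested, 606 and 389 were shared. Leaving out 1 library at a time gave 638 to 836 higher and 582 to 756 lower genes. The replicate block gave 750 higher and 677 lower genes. Whether the numbers pair the libraries was not decided. Deviations of same-numbered libraries correlated at 0.0389, -0.0063 and -0.0506 over 2976 genes, and only 1 of 3 uninjured libraries correlated best with its own number. These deviations are almost all counting noise, so correlations near 0 would arise with or without pairing. The balance moved: of the calls, 52.9% were higher with TMM, 60.3% with library totals alone (927 and 610), 62.0% without a filter (948 and 582), 57.2% with DESeq2 (801 and 599) and 47.7% with limma-voom (665 and 729). The exceptions were the assumed spreads: with 1 summed sample per group and an assumed coefficient of variation of 0.2, 305 genes were higher and 176 lower, and with 0.4, 42 and 5, because the assumed spread exceeds that between the libraries. The exact binomial test on the summed counts, which uses counting error alone, called 814 and 744. All 72 values of the 4 named genes kept their direction and their side of the threshold. For ENSMUSG00000106268, which had 0 uninjured counts, the log2 fold change of 8.68 became 6.14 with limma-voom and 7.64 with DESeq2. With either assumed coefficient of variation it was 10.3. For ENSMUSG00000078735 the log2 fold change of -5.73 became -7.95 without the second injured library, which held its only injured counts. For ENSMUSG00000028949 it went from -3.71 to -3.10 without the first and -4.42 without the second injured library, and to -2.85 with injured libraries thinned. The gene lists, the share tests and the removal of mitochondrial genes and haemoglobins were not run, since the identifiers were not paired with symbols, and alternatives for normalized units did not apply to counts. In data simulated at this depth and number of libraries, with the spread between libraries, 17.9% of genes changed 1.5-fold were recovered. Neither depth nor spread was varied there.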

Other observations

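The tests of how the libraries of a group came to agree, of genes that disagreed in both groups and of shares by identifier number were chosen only after the result was seen. Genes whose Ensembl identifier is numbered 100000 or higher held 14.4% of the counts in the uninjured group (95% Wilson interval 14.3% to 14.5%) and 11.3% in the injured group (11.2% to 11.3%). The shares were 14.2% to 14.5% in the 3 uninjured and 11.2% to 11.3% in the 3 injured libraries. The difference lay in 5 of the 10 most abundant genes, all 5 lower in the injured reads, which together held 6.95% of the uninjured and 2.77% of the injured counts. The other identifiers of this range went the opposite way, from 7.44% to 8.48%, and of the 209 tested in the range, 76 were called higher and 52 lower.

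The 3 libraries of each group differed in total and in nearly all genes by little more than counting noise. Whether 1 pool of reads per group was divided into 3 parts before quantification was not decided. The agreement of the totals and the coefficient of variation of 3.57% do not exclude it. They are the pattern that raised the question, so they were not taken as support for it. A random division of finished counts is argued against, since 6.32% of the uninjured and 6.08% of the injured genes differed between libraries at an unadjusted chi-square p under 0.05, above the highest of 100 random divisions (5.75% and 5.56%). Separate libraries made from 1 extract are not excluded, but their totals would have to match within counting noise. The SD of the totals was 231 counts in the uninjured group, against 278.5 for a random division of 1 pool. In the injured group it was 297 against 376. The labels do not say which of these origins applies. For the genes called by edgeR, only the real split among the 10 splits of the 6 libraries gave as many (1485), and the highest of the others gave 0. The 10 splits are too few for a share under 0.05. With the libraries of a group counted as 1 sample, the other splits mix the same 2 samples and do not bear on chance between samples.

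The injured profile was spread over more genes. Greater depth alone is argued against, since an excess of 11.7% of genes remained at equal depth, where the lowest of 100 draws (11822) lay above the uninjured number (10636). The 10 most abundant genes drawing counts away from the rest of the uninjured group are argued against too, since 93.0% of the excess remained without them. An effect of injury on the RNAs bound or present, more unspecific RNA in 1 of the precipitates, a different mix of cells and any difference between the 2 preparations stay open, as none was tested and each group is 1 sample.

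A few genes disagreed between the libraries of a group far beyond counting noise, 19 in the uninjured and 22 in the injured group, where 0.383 and 0.615 would be expected by chance. Of these, 15 and 13 had 0 counts in at least 1 library; ENSMUSG00000025508, for example, had 0, 93 and 0 counts in the uninjured and 66, 346 and 250 in the injured libraries. Among the genes measured in both groups, 3 disagreed in both, of 13 and 9 among 3562, against 0.0328 expected of independent lists (Fisher's exact test, one-sided p = 3.15e-06); the others were ENSMUSG00000045690 and ENSMUSG00000021057, all singled out after their values were seen. A property of the gene that recurs in both groups, such as a model that overlaps or resembles another, is consistent with this. Whether the reads moved among these same genes cannot be told apart from chance: their summed counts were as even in 11.6% of random arrangements for the uninjured and 7.26% for the injured group, and reads that went to genes outside the list would not show in this test.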
